A study of Homo sapiens with 40 samples.

How the data were processed

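Total RNA of 786-0 cells with SETD2 intact (WT) or knocked out (KO) was sequenced in 40 libraries, 2 for each of 20 groups of line, treatment and day. Libraries were made with a KAPA RNA HyperPrep kit per the labels. The deposited table holds raw counts: whole numbers of fragments per gene, with no normalization by the authors. Per the file header the counts came from featureCounts 1.5.0-p1 with the Ensembl 104 annotation of GRCh38, strand setting 1, a mapping quality of at least 20, primary alignments only and reads marked as duplicates ignored. The header names 76 alignments, of which the table holds 40. The processing notes of the authors name FastQC, Trimmomatic, Partek and featureCounts, and STAR appears only in the names of the alignments. Each library was matched to its group through the labels, and no column was left unmatched. One passage of the labels spells the PARP inhibitor BMN673 as a different number.

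The deposited table holds 60664 genes, and 42028 of them have a symbol. The table lists 37 mitochondrial genes, all with 0 counts, so no mitochondrial share was computed. Totals ran from 17833960 to 22631101 counts per library, and the 10 highest genes of a library took 4.412% to 6.305% of its counts. Over 26 antisense pairs the median density of the antisense gene was 0.02115 of its partner's, so the strand setting separated strands. A group with 0 counts in its 2 libraries was given a floor of 3 counts in each library, which is 0.136 to 0.167 CPM across groups. Folds against a group at 0 are given as lower bounds from that floor. Floors cover counting error only.

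Genes were kept by edgeR's filterByExpr over the 20 groups (minimum count 10, minimum total 15), which left 22527. Counts were scaled by TMM and all 40 libraries entered one edgeR quasi-likelihood fit with a mean per group (edgeR 4.0.16, R 4.3.3), with 20 residual degrees of freedom, 12.37 prior degrees of freedom, a common dispersion of 0.005152 and a biological coefficient of variation of 0.07178. The 28 contrasts compared KO with WT at day 0; each drug and the combination with control at days 5, 16 and 26 in each line; the combination with DAC and DAC with BMN averaged over days in each line; day 26 with day 5 of DAC in each line; and the difference of the response to each treatment between KO and WT averaged over days. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene passed at an adjusted p below 0.05. In contrasts averaged over days, CPM are means of the 3 day means, while the log2 value averages the 3 daily log2 differences. Log2 values shown for single libraries use a prior count of 2.

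A set of 17 gene lists holding 511 genes was written before the data were examined, as were the contrasts, the naming rule and the first group of settings below. The lists cover interferon-stimulated genes, nucleic acid sensing, MHC class I antigen presentation, cancer-testis and germline genes, endogenous retroviral genes, p53 targets, homologous recombination and Fanconi genes, proliferation, DNA methylation machinery, H3K36 methylation, inflammatory cytokines and NF-kB targets, hypoxia-inducible genes, epithelial-mesenchymal genes, renal tubule genes, genes described as promoter-methylated in cancer, markers of blood and endothelial cells, and stress response. Lists were tested by limma's camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 17 lists of a contrast, and again with an estimated correlation. A list given with a single p that passes also passed with the estimated correlation; where it did not, the second p is printed. Some genes stand in more than 1 list, and several lists move together, so list calls are not independent of one another.

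Genes were named by a rule. In 8 main comparisons (KO against WT at day 0, DAC and the combination against control at day 5 in each line, the combination against DAC in each line and the response to DAC between lines) SETD2 came first, then the 8 largest rises and 8 largest falls among genes that passed and up to 4 members of each list that passed. In the other comparisons the numbers were 3, 3 and 2. Members of the interferon, cancer-testis and p53 lists were always named in the main comparisons, and DNMT1, DNMT3B, UHRF1, PARP1 and PARP2 always where a drug was tested. A largest rise or fall needed a symbol, at least 3 counts in every library compared, a mean of at least 5 CPM in the higher group and no overlap of the libraries. The genes printed are a choice among those the rule named. A few results that the rule named are not reported. Genes with near-identical copies (MAGE-A and SPANX families, IFITM1, HLA genes, histone genes and pseudogenes) are uncertain where reads could be shared.

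The fit was tested on simulated data with known changes, built on the design of DAC at day 5 in WT (20711 genes). It recovered 44 of 67 genes changed 1.5-fold (65.7%), 66 of 67 changed 2-fold (98.5%) and 66 of 66 changed 4-fold. There were 7 false calls, and the fit called 0 genes and 0 of 30 lists where nothing had been changed. Changed genes were drawn from well-counted genes only, the dispersion was the same for every gene, and no trend with GC content was built in. The recovery and false calls therefore do not carry over to low counts or to the GC-linked spread of the real libraries.

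Replicates correlated at Pearson r 0.987 to 0.991 across genes, which are not independent replicates, and the chi-square per degree of freedom between them ran from 1.75 to 30.6, highest in the WT controls. The first axis of the within-group differences held 43.5% of their variance and followed the GC content of genes (Spearman 0.888 across genes, against 0.197 for length, with values for 99.9% of 10500 genes). Replicate numbers did not pair libraries across groups: the correlations of within-group differences ran from -0.659 to 0.769 over 190 pairs of groups, with a median of 0.000493. A replicate number used as a block was therefore an alternative only.

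The settings changed one at a time were RLE size factors, no filter on low counts, DESeq2's Wald test (1.42.0) and a replicate block. Others were fits with only the libraries of a contrast, a term for a lane suffix carried by 17 of the library names, and each library left out in turn. For lists they were the estimated correlation and the block. Fits with fewer libraries also applied the filter on low counts anew, so the genes tested changed along with the libraries. Chosen after the data had been seen were offsets for GC content (lowess with span 0.3 on genes above a log2 CPM of 3, GC from GENCODE release 29), day-averaged contrasts with days 5 and 16 only, tests of the combination against DAC at each day, and splits of the libraries with the mean difference between the lines as an offset. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.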

Results

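RNA sequencing of total RNA was deposited for 786-0, a line of clear cell renal cell carcinoma, in a form with SETD2 intact (WT) and a form labelled as a SETD2 knockout (KO). SETD2 is the enzyme that places 3 methyl groups on lysine 36 of histone H3. Cells were left untreated at day 0 or treated with 100 nM DAC (decitabine, an inhibitor of DNA methyltransferases), 10 nM BMN (BMN673, talazoparib, an inhibitor of PARP enzymes), or both, for 5, 16 or 26 days. The 20 groups held 2 libraries each, 40 in all, and the labels do not state whether the replicates of a group were separate cultures. Counts per library summed to between 17833960 and 22631101 over 60664 genes, of which 22527 were tested. No untreated cells were sampled after day 0, so every comparison with control carries the time in culture along with the treatment. The combination and each single drug, by contrast, were sampled on the same days. The series title gives its subject as inhibition of both DNA methylation and PARP in SETD2-deficient kidney cancer. CPM (counts-per-million units) below are given as the mean ± SD of the 2 replicates, and log2 fold changes carry their SE.

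SETD2 itself (ENSG00000181555, GRCh38 chromosome 3, 47016429 to 47164113, minus strand) was measured at 127 ± 20 CPM in KO and 139 ± 14 CPM in WT controls. The log2 difference of -0.13 ± 0.07 did not pass (adjusted p = 0.2). The level of this transcript therefore does not tell the lines apart, and gene counts give no view of an edited sequence. Across the 20 groups its mean ran from 111 CPM (KO, combination, day 5) to 175 CPM (WT, BMN, day 26). The genes followed in every drug comparison were DNMT1 (ENSG00000130816, chromosome 19, 10133342 to 10231286) and DNMT3B (ENSG00000088305, chromosome 20, 32762385 to 32809356), both DNA methyltransferases, and UHRF1 (ENSG00000276043, chromosome 19, 4903080 to 4962154), which brings DNMT1 to newly copied DNA. On the PARP side they were PARP1 (ENSG00000143799, chromosome 1, 226360210 to 226408154) and PARP2 (ENSG00000129484, chromosome 14, 20343615 to 20357904).

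The first question was how the untreated KO cells differed from the untreated WT cells. The leukocyte actin-bundling gene LCP1 had the largest rise, to 170 ± 12 CPM in KO from 1.15 ± 0.014 CPM in WT (log2 7.20 ± 0.13, adjusted p = 3.1e-29). The cytokine gene TNF stood at 20.8 ± 0.65 against 0.747 ± 0.63 CPM (log2 4.80 ± 0.23), and the arginine transporter gene SLC7A2 at 28.2 ± 2.5 against 0.381 ± 0.17 CPM (log2 6.18 ± 0.29). The BMP antagonist gene CHRDL1 was lower in KO, at 0.817 ± 0.065 against 57.6 ± 3.3 CPM (log2 -6.13 ± 0.16), as was the GTPase regulator gene DOCK11 (log2 -6.14 ± 0.27). The other genes named by size were AFF2, EPPK1, VPS9D1-AS1 and MARK1 above WT (log2 4.98 to 5.46) and SLC38A5, USH1C, CYB5A, GNG4, ADAMTS12 and EPB41L4A below it (log2 -6.12 to -5.48). The histone gene H4C13 (log2 5.71) has near-identical copies and is uncertain. In all, 6136 genes differed, 3008 higher and 3128 lower in KO (a balance that turned in 5 of 11 settings, with 3409 and 2687 without WT control replicate 2), and of these 667 were at least 2-fold higher and 1273 at least 2-fold lower. One line of each form was sampled, so these differences belong to the pair of lines and not to SETD2 alone.

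By gene lists fixed in advance, inflammatory cytokines and NF-kB targets were higher in KO. Of 33 measured, 21 were higher and 5 lower (21 and 5 adjusted over the list alone; list adjusted p = 2.7e-16). The neutrophil attractant CXCL8 stood at 73.3 ± 0.43 against 2.78 ± 0.49 CPM and the adhesion gene ICAM1 at 404 ± 16 against 148 ± 10 CPM, while complement C3 was lower at 9.45 ± 1.4 against 56.2 ± 0.077 CPM. Of 27 p53 target genes 17 were higher and 4 lower (17 and 4 adjusted over the list alone; adjusted p = 4.4e-05). The growth-arrest gene GADD45A was at log2 1.14 ± 0.09 and the death receptor gene FAS at log2 1.40 ± 0.12. Hypoxia-inducible genes had 13 of 28 higher and 4 lower (adjusted p = 1.5e-05, adjusted p = 0.21 with an estimated correlation), with CA12 at log2 1.85 ± 0.06 and PFKFB3 at log2 -1.09 ± 0.07. Their median log2 was 0.23 and their test pointed up, while their mean was -0.01. Antigen presentation by MHC class I had 9 of 17 higher and 1 lower (adjusted p = 0.0033, adjusted p = 0.33 with an estimated correlation). The stress response list had 12 of 24 higher and 4 lower (adjusted p = 0.0033, adjusted p = 0.34 with an estimated correlation), including IER3 at log2 1.55 ± 0.08. Interferon-stimulated genes did not differ as a list (7 of 37 higher, 11 lower, adjusted p = 0.097). Of these OAS1 (log2 -4.05 ± 0.37), HERC5 (log2 -3.28 ± 0.19) and IFI27 (log2 -2.97 ± 0.15) were lower in KO. Cancer-testis and germline genes had 0 of 41 higher and 6 lower (adjusted p = 0.35). Of these, MAGEA3 had 0 counts in the KO controls and 3.41 ± 0.9 CPM in WT, and MAGEA6 had 0.136 ± 0.037 against 6.86 ± 1.1 CPM. The pair share near-identical sequence and their separate levels are uncertain. The remaining lists did not pass: proliferation (13 of 37 higher, 2 lower, adjusted p = 0.065), renal tubule genes (3 of 18 higher, 7 lower, adjusted p = 0.097), endogenous retroviral genes (0 of 12 higher, 4 lower, adjusted p = 0.35) and epithelial-mesenchymal genes (12 of 31 higher, 13 lower, adjusted p = 0.39). Nor did genes described as promoter-methylated in cancer (9 of 30 higher, 7 lower, adjusted p = 0.69), markers of blood and endothelial cells (2 of 12 higher, 0 lower, adjusted p = 0.69) or homologous recombination and Fanconi genes (9 of 44 higher, 6 lower, adjusted p = 0.73). The last 3 were nucleic acid sensing (0 of 16 higher, 4 lower, adjusted p = 0.73), writers, readers and erasers of H3K36 methylation (4 of 26 higher, 4 lower, adjusted p = 0.73) and DNA methylation machinery (5 of 17 higher, 3 lower, adjusted p = 0.97).

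The next comparisons asked what DAC changed after 5 days. In WT cells the fibrillar collagen gene COL5A1 went from 0.308 ± 0.15 to 401 ± 30 CPM (log2 10.32 ± 0.16, adjusted p = 1.8e-31) and COL1A1 from 14 ± 0.74 to 1890 ± 170 CPM (log2 7.07 ± 0.13). THY1, a surface glycoprotein gene of fibroblasts and T cells, rose to 70.1 ± 3.1 from 0.589 ± 0.12 CPM, and GCNA, a gene of germ cells, to 66.2 ± 2.2 from 0.871 ± 0.23 CPM. PROSER2-AS1, AFAP1-AS1, MXRA8 and MYO1G rose by log2 6.25 to 8.16. Falls were smaller: VAV3, a guanine nucleotide exchange factor gene, went to 1.74 ± 0.62 from 25.1 ± 0.85 CPM (log2 -3.86 ± 0.25) and PPARGC1A, a regulator of mitochondrial genes, to 2.3 ± 0.62 from 13.9 ± 0.02 CPM. The falls of LINC02532, DIRAS2, AKR1C3, SFRP4 and HOGA1 lay between log2 -2.64 and -2.11. Of 6272 genes that passed, 3518 were higher and 2754 lower, and at 2-fold or more the numbers were 2064 higher and 334 lower. Without WT control replicate 1 fewer genes were higher (2729) than lower (3385).

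Cancer-testis and germline genes, which DNA methylation keeps silent in most tissues, formed the clearest list in WT at day 5: 41 of 41 were higher (adjusted p = 3.1e-99). With members at 0 in control set to the floor, their median rise was 25.6-fold. The germline gene MAGEA4 rose to 23.4 ± 1.1 CPM, at least 152-fold, and PNMA5 to 29.5 ± 1.2 CPM, at least 193-fold, each from 0 counts in control. MAEL, which acts on transposons in the germline, rose by log2 5.75 ± 0.24. Interferon-stimulated genes had 35 of 37 higher and 1 lower (36 and 1 adjusted over the list alone; adjusted p = 1.7e-68, median log2 1.81). The RNA sensor OAS2 stood at 11.2 ± 0.54 against 0.103 ± 0.074 CPM, MX2 at log2 4.08 ± 0.16 and IFI27 at 66.5 ± 0.06 against 9.45 ± 0.18 CPM. The NF-kB list had 27 of 33 higher and 0 lower (adjusted p = 2.8e-43). IL6 stood at 17.8 ± 0.84 against 1.2 ± 0.45 CPM and C3 at 493 ± 30 against 56.2 ± 0.077 CPM. MHC class I antigen presentation had 16 of 17 higher (adjusted p = 4e-11; TAP1 log2 1.30 ± 0.09, B2M log2 0.59 ± 0.06) and nucleic acid sensing 12 of 16 higher and 1 lower (adjusted p = 2.4e-06; IFIH1 log2 1.59 ± 0.13). Epithelial-mesenchymal genes had 19 of 31 higher and 3 lower (adjusted p = 1.3e-23), the epithelial CDH1 (log2 5.39 ± 0.27) included. Genes described as promoter-methylated had 14 of 30 higher and 7 lower (adjusted p = 7.8e-06; XAF1 log2 2.54 ± 0.13, BNC1 log2 6.99 ± 0.42). The stress list (12 of 24 higher, 3 lower, adjusted p = 0.0086, adjusted p = 0.34 with an estimated correlation) and proliferation (1 of 37 higher, 6 lower, adjusted p = 0.038, adjusted p = 0.32 with an estimated correlation) passed at the preset correlation alone. The p53 targets did not pass as a list (9 of 27 higher, 2 lower, adjusted p = 0.12). GDF15 nonetheless rose to 15 ± 0.49 from 6.38 ± 2.2 CPM and FAS by log2 0.95 ± 0.12. Among the genes followed in every drug comparison DNMT3B rose to 67.1 ± 1.9 from 41 ± 7.5 CPM (log2 0.71 ± 0.10) and UHRF1 by log2 0.48 ± 0.08. PARP1 did not pass (log2 0.12 ± 0.07, adjusted p = 0.2). DNMT1 (log2 0.21 ± 0.07) and PARP2 (log2 -0.37 ± 0.11) passed. The DNMT1 call was lost without any 1 of the 4 libraries compared and the PARP2 call without control replicate 1 or DAC replicate 2. With only the 4 libraries of the contrast fitted, 2958 genes passed in WT.

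In KO cells DAC at day 5 raised COL5A1 to 530 ± 26 from 0.764 ± 0.011 CPM (log2 9.43 ± 0.14, adjusted p = 9.9e-32), COL1A1 to 1070 ± 120 from 6.38 ± 0.06 CPM, and the endothelial TGF-beta co-receptor gene ENG to 75.7 ± 6.2 from 0.52 ± 0.2 CPM (log2 7.17 ± 0.22). THY1, AFAP1-AS1, GCNA, MAEL and UNC13D rose by log2 6.29 to 6.85. LINC02532 fell to 0.326 ± 0.083 from 18.2 ± 0.23 CPM (log2 -5.78 ± 0.28), and VAV3, KMO, DIRAS2, MYH13, ARHGAP6 and ANO3 by log2 values from -4.62 to -3.42. The tubule cadherin gene CDH6 fell to 56.6 ± 5.3 from 222 ± 19 CPM. The calls numbered 7977, with 4383 higher and 3594 lower, 2382 and 599 of them by at least 2-fold.

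The KO lists at day 5 of DAC were led by cancer-testis and germline genes (40 of 41 higher, adjusted p = 2.4e-72, median 24.6-fold with zeros at the floor). PNMA5 reached 63.8 ± 0.19 CPM, at least 390-fold above control, and MAGEA4 at 22.4 ± 0.56 CPM, at least 137-fold. Interferon-stimulated genes had 35 of 37 higher and 1 lower (adjusted p = 1.1e-43, median log2 2.03). Among them were IFI27 at log2 4.64 ± 0.13, MX2 at 5.52 ± 0.18 and EPSTI1 at 5.05 ± 0.20. The NF-kB list had 29 of 33 higher and 1 lower (adjusted p = 1.4e-32; CXCL8 388 ± 29 against 73.3 ± 0.43 CPM). Epithelial-mesenchymal genes had 23 of 31 higher and 3 lower (adjusted p = 2e-38; COL6A3 290 ± 9.9 against 13.4 ± 0.12 CPM). MHC class I presentation (12 of 17 higher, 1 lower, adjusted p = 3.6e-09; NLRC5 log2 1.86 ± 0.11) and nucleic acid sensing (12 of 16 higher, 2 lower, adjusted p = 0.00067; CGAS log2 0.87 ± 0.10) passed. Proliferation genes had 0 of 37 higher and 17 lower (adjusted p = 0.0061, adjusted p = 0.16 with an estimated correlation). FOXM1 was at log2 -0.49 ± 0.07 and MCM6 at -0.32 ± 0.06. Renal tubule genes split, 6 of 18 higher and 8 lower (adjusted p = 0.012, adjusted p = 0.086 with an estimated correlation). Their median log2 was -0.43 and their test pointed down, while their mean was 0.52. ANPEP, a brush-border peptidase gene, rose to 15.6 ± 0.52 from 0.027 ± 0.038 CPM. Promoter-methylated genes had 16 of 30 higher and 8 lower (adjusted p = 0.00071, adjusted p = 0.086 with an estimated correlation). The neurofilament gene NEFL fell to 28.8 ± 3.6 from 135 ± 1.1 CPM. The p53 list did not pass (10 of 27 higher, 6 lower, adjusted p = 0.53). UHRF1 (log2 0.12 ± 0.08, adjusted p = 0.27) and PARP1 (log2 0.03 ± 0.07, adjusted p = 0.8) did not pass. The calls of DNMT1 (log2 0.18), DNMT3B (log2 0.24) and PARP2 (log2 -0.37) were each lost in some leave-one-out fits, all 3 without at least 1 of the KO control libraries.

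**Figure D1:**
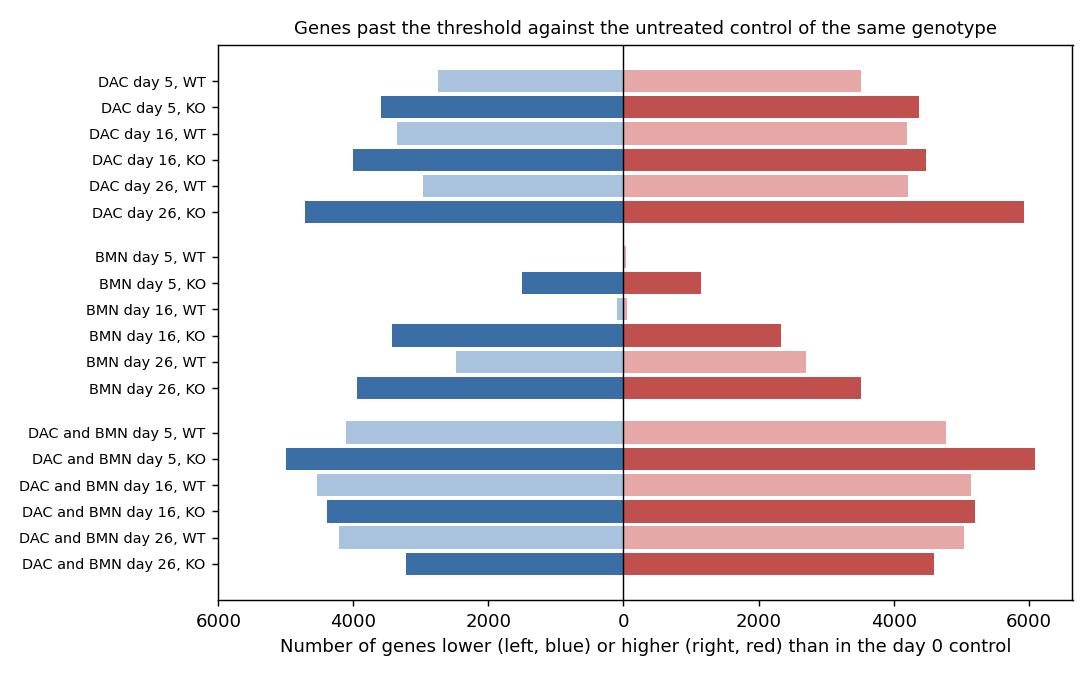
Genes lower (left) and higher (right) than the day 0 control of the same line in each treated group, with WT in light and KO in dark bars. BMN alone called 42 genes in WT and 2639 in KO at day 5, while DAC called 6272 and 7977.

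At days 16 and 26 the response to DAC continued. In WT, COL5A1 stood at 821 ± 22 CPM at day 16 and 552 ± 79 CPM at day 26. The interferon-stimulated genes EPSTI1 (log2 8.03 ± 0.18 at day 16) and OAS2 (258 ± 4.9 CPM at day 26, log2 11.22 ± 0.18) were among the largest rises. SFRP4, a secreted Wnt antagonist gene, had fallen by day 16 (log2 -4.69 ± 0.37) and ACSM2A, a renal acyl-CoA synthetase gene, by day 26 (log2 -5.65 ± 0.44). The WT calls numbered 7547 at day 16 (4199 higher, 3348 lower) and 7186 at day 26 (4216 higher, 2970 lower). Without WT control replicate 1 the balance turned at both days (3546 higher and 4122 lower, 3385 and 3999), and at day 26 also without DAC replicate 2 (3508 and 3668). All 37 interferon-stimulated genes were higher at both days in WT (median log2 3.66 and 3.53). Hypoxia-inducible genes were higher at day 16 (16 of 28 higher, 5 lower, adjusted p = 1e-08; VEGFA 667 ± 23 against 215 ± 21 CPM). In KO, COL5A1 reached 1350 ± 0.69 CPM at day 16 and 952 ± 28 CPM at day 26, and OAS1, at 0.219 ± 0.08 CPM in control, 218 ± 1.7 and 203 ± 2.8 CPM. The retinaldehyde dehydrogenase gene ALDH1A1 fell to 10.1 ± 0.52 from 307 ± 19 CPM by day 16 and the retinol pathway gene DHRS3 to 2.67 ± 0.013 from 31.6 ± 0.97 CPM by day 26. KO calls numbered 8485 (4484 higher, 4001 lower) and 10639 (5926 higher, 4713 lower), the latter with a median log2 of 0.114 over all genes tested. Without KO control replicate 2 the balance turned at both days (3394 higher and 3681 lower, 3885 and 4687), and at day 26 also without DAC replicate 2 (4325 and 4684) and with only the contrast's libraries (4859 and 4898). All 37 interferon-stimulated genes were higher at day 16 in KO (median log2 4.31). Proliferation genes were lower in KO at day 16 (2 of 37 higher, 26 lower, adjusted p = 9.9e-05, adjusted p = 0.066 with an estimated correlation) and at day 26 (2 higher, 26 lower, adjusted p = 2.8e-07). By day 26 MYBL2, an S-phase transcription factor gene, had log2 -0.90 ± 0.08 and PARP1 had fallen to 272 ± 1.2 from 382 ± 48 CPM (log2 -0.49 ± 0.07). The WT count at day 16 was 4498, and at day 26 it was 2392, with only the libraries of the contrast fitted.

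Between day 5 and day 26 of DAC the interferon list grew and the germline list shrank. OAS2 went from 11.2 to 258 CPM in WT (log2 4.53) and from 7.52 to 299 CPM in KO (log2 5.31). The collagen gene COL3A1 went from 1.1 to 26.9 CPM in WT and from 0.352 to 29.4 CPM in KO. GCNA dropped from 66.2 to 2.43 CPM in WT (log2 -4.77) and by a log2 of -4.35 in KO, where the co-stimulatory receptor gene TNFRSF4 fell most (log2 -4.97). Of 37 interferon-stimulated genes 36 rose in WT (median log2 1.75) and 35 in KO (median 2.05, adjusted p = 2.3e-247), with 0 falling in either. Cancer-testis genes had 5 of 41 higher and 17 lower in WT (median log2 -0.49, adjusted p = 4.8e-08; MAGEA4 log2 -1.72). In KO the numbers were 3 higher and 25 lower (median -0.92, adjusted p = 2.2e-12; DAZL log2 -3.77). NF-kB targets had 4 of 33 higher and 13 lower in WT (adjusted p = 0.00044) and 4 higher and 24 lower in KO (adjusted p = 1.6e-21; ICAM1 log2 -1.57). Stress genes (1 of 24 higher, 15 lower, adjusted p = 4.8e-09) fell and endogenous retroviral genes (4 of 12 higher, 0 lower, adjusted p = 0.011; PEG10 log2 1.23) rose in KO. In all 4898 genes differed in WT (2839 higher, 2059 lower, or 2592 and 2966 with GC offsets) and 8096 in KO (4085 higher, 4011 lower, which turned in 8 of 11 settings, with 3614 and 4358 with RLE size factors). The WT count was 2759 without WT DAC day 5 replicate 1, 3104 without its replicate 2, 3071 without WT DAC day 26 replicate 1 and 1493 with only its own 4 libraries. Fewer genes were higher than lower in that last fit (706 and 787) and without WT replicate 2 of day 5 (1507 and 1597) or day 26 (2323 and 2469).

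BMN alone was tested for what PARP inhibition changed by itself. In WT at day 5 the cell-cycle inhibitor gene CDKN1A, a p53 target, rose to 148 ± 4.3 from 85 ± 10 CPM (log2 0.80 ± 0.09, adjusted p = 1.9e-06), IL6 to 3.95 ± 1.3 from 1.2 ± 0.45 CPM (log2 1.70 ± 0.23) and the collagen gene COL6A3 to 235 ± 10 from 171 ± 7.4 CPM (log2 0.45 ± 0.06). These 3 calls held without any 1 of the 4 libraries. The falls of TXNIP, DHRS3 and OLMALINC (log2 -0.50 to -0.43) and the rises of SAA1 and GAS6-AS1 did not hold without BMN replicate 1, nor in other such fits. Of 42 genes called, 33 were higher and 9 lower, with 1499 at an unadjusted p below 0.05. The count was 12 without BMN replicate 1, 14 without BMN replicate 2 and 104 without control replicate 2. Of the p53 targets 2 of 27 were higher (13 adjusted over the list alone; adjusted p = 1e-19) and of interferon-stimulated genes 3 of 37 (10 adjusted over the list alone; adjusted p = 3.4e-10), with 0 lower in each. NF-kB targets had 2 of 33 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 2.6e-08). Epithelial-mesenchymal genes had 3 of 31 higher (8 adjusted over the list alone; adjusted p = 2.8e-06, adjusted p = 0.099 with an estimated correlation). At day 16 in WT 154 genes passed (58 higher, 96 lower, or 755 and 593 without a filter). The fall of the hypoxia-inducible gene NDRG1, at 741 ± 5.8 against 1010 ± 78 CPM (log2 -0.44 ± 0.06), held without any 1 library. The hypoxia list had 0 of 28 higher and 2 lower (4 adjusted over the list alone; adjusted p = 0.00034, adjusted p = 0.57 with an estimated correlation). The homologous recombination and Fanconi list passed (adjusted p = 0.037, adjusted p = 0.57 with an estimated correlation) with 0 of 44 members passing singly. By edgeR with only the 4 libraries of each contrast 0 genes passed at day 5 or day 16, against 1499 and 4223 genes at an unadjusted p below 0.05 in the fit of all 40 libraries and 70 and 986 genes by DESeq2. The day 16 count was 3987 without WT control replicate 1, 11 without control replicate 2, 11 without BMN replicate 2 and 9 without BMN replicate 1.

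At day 26 of BMN in WT 5188 genes passed, 2704 higher and 2484 lower. The immunoglobulin-like gene IGFN1 rose to 1960 ± 28 from 450 ± 170 CPM (log2 2.12 ± 0.14), and the mTOR inhibitor gene DDIT4 fell to 144 ± 3.2 from 433 ± 80 CPM (log2 -1.59 ± 0.08). Hypoxia-inducible genes had 0 of 28 higher and 17 lower (adjusted p = 7.9e-17). NDRG1 stood at 362 ± 17 against 1010 ± 78 CPM and EGLN3, which tags HIF for destruction, at log2 -1.21 ± 0.08. MHC class I genes (1 of 17 higher, 11 lower, adjusted p = 0.00018), promoter-methylated genes (2 of 30 higher, 9 lower, adjusted p = 0.00046) and endogenous retroviral genes (5 of 12 higher, 2 lower, adjusted p = 0.044; PEG10 log2 0.75 ± 0.05) each had an adjusted p = 0.14 with an estimated correlation. Homologous recombination genes had 14 of 44 higher and 1 lower (adjusted p = 0.0018, adjusted p = 0.21 with an estimated correlation). The count fell to 2083 without WT control replicate 2, to 2544 without BMN replicate 1 and to 362 with only the contrast's libraries. Which direction held more genes turned in 7 of 11 settings, with 2381 higher and 2800 lower with RLE size factors and 2099 and 3975 without WT control replicate 1.

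In KO cells BMN at day 5 lowered NDRG1 to 343 ± 0.8 from 1150 ± 18 CPM (log2 -1.74 ± 0.07, adjusted p = 3.1e-19), VAV3 to 2.32 ± 0.26 from 17.5 ± 0.91 CPM (log2 -2.91 ± 0.25) and SLC7A2 to 3.96 ± 1.5 from 28.2 ± 2.5 CPM (log2 -2.83 ± 0.20). CDKN1A rose to 172 ± 4.3 from 120 ± 5.8 CPM (log2 0.52 ± 0.08) and RRM2B, which supplies nucleotides for repair, to 89.9 ± 2.5 from 49 ± 1.5 CPM. The largest rises, of MTND4LP30, SNORD3C and ATP1B3P1 (log2 1.68 to 2.81), belong to pseudogenes or repeated small RNAs and are uncertain, and the calls of SNORD3C and ATP1B3P1 were lost without control replicate 1. The calls numbered 2639, 1142 higher and 1497 lower (1712 and 1512 with only the contrast's libraries). Hypoxia-inducible genes had 0 of 28 higher and 14 lower (adjusted p = 2.9e-18) and p53 targets 11 of 27 higher and 0 lower (14 and 1 adjusted over the list alone; adjusted p = 6.2e-05). NF-kB targets had 9 of 33 higher and 1 lower (adjusted p = 0.00016; CXCL8 log2 0.72 ± 0.10) and renal tubule genes 0 of 18 higher and 6 lower (adjusted p = 0.00015; HAVCR1 log2 -0.44 ± 0.05). MHC class I (1 of 17 higher, 3 lower, adjusted p = 0.0034, adjusted p = 0.3 with an estimated correlation) and epithelial-mesenchymal genes (5 of 31 higher, 3 lower, adjusted p = 0.025, adjusted p = 0.59 with an estimated correlation) passed at the preset correlation alone. At day 16, with 5749 calls (2326 higher, 3423 lower), CDKN1A lay below control, at 61.1 ± 0.31 CPM (log2 -0.97 ± 0.09). Also lower were p53 targets (1 of 27 higher, 9 lower, adjusted p = 0.0048, adjusted p = 0.17 with an estimated correlation), hypoxia-inducible genes (1 of 28 higher, 14 lower, adjusted p = 2e-08) and renal tubule genes (1 of 18 higher, 9 lower, adjusted p = 0.0024), the latter pair each at an adjusted p = 0.087 with an estimated correlation. At day 26, with 7463 calls (3513 higher, 3950 lower), NDRG1 had dropped to 244 ± 1.6 CPM (log2 -2.23 ± 0.07), EGLN3 to 45.9 ± 3.0 from 149 ± 3.0 CPM, and DHRS3 to 4.94 ± 0.5 CPM (log2 -2.68 ± 0.11). DNMT3B fell to 33.1 ± 1.4 from 55.8 ± 0.99 CPM (log2 -0.75 ± 0.10) and the peptide-loading gene TAPBP by a log2 of -1.02 ± 0.07. Hypoxia-inducible genes (0 of 28 higher, 17 lower, adjusted p = 4.7e-22), MHC class I (1 of 17 higher, 14 lower, adjusted p = 1.8e-11) and renal tubule genes (0 of 18 higher, 11 lower, adjusted p = 2.2e-06) were lower. Each library left out lowered the day 5 count: to 817 without BMN replicate 1, 1356 without BMN replicate 2, 1102 without control replicate 1 and 1698 without control replicate 2. The day 16 count was 2941 without BMN replicate 2, 3469 without control replicate 2 and 2477 with GC offsets, and the day 26 count 4855 without BMN replicate 1.

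The combination was compared with control next. In WT at day 5 COL5A1 reached 297 ± 5.9 CPM (log2 9.89 ± 0.16) and MX2, an interferon-induced GTPase gene, 75.8 ± 0.17 CPM (log2 6.77 ± 0.13). LAPTM5, a lysosomal gene of blood cells, rose to 47.3 ± 0.58 from 0.283 ± 0.19 CPM. ALDH1A1 fell to 97.8 ± 5 from 810 ± 30 CPM (log2 -3.05 ± 0.06), VAV3 to 0.682 ± 0.052 CPM (log2 -5.19 ± 0.30) and the inositol phosphatase gene IMPA2 to 9.72 ± 1.5 from 76.1 ± 7.8 CPM. Of 8888 genes called, 4782 were higher and 4106 lower, 2743 and 720 of them by at least 2-fold. Without WT control replicate 1 the numbers were 3752 higher and 4160 lower. Interferon-stimulated genes had 36 of 37 higher (adjusted p = 3.2e-189, median log2 3.45; OAS2 112 ± 1.4 against 0.103 ± 0.074 CPM) and NF-kB targets 31 of 33 (adjusted p = 1.2e-82; IL6 120 ± 4.1 against 1.2 ± 0.45 CPM), with 0 lower in each. The p53 targets had 20 of 27 higher and 0 lower (adjusted p = 1.2e-11), and MHC class I 17 of 17 higher (adjusted p = 3.4e-24). GDF15, a stress cytokine gene under p53, rose to 110 ± 1.4 from 6.38 ± 2.2 CPM (log2 4.11 ± 0.16) and CDKN1A to 293 ± 23 from 85 ± 10 CPM (log2 1.79 ± 0.09). Cancer-testis genes had 40 of 41 higher (adjusted p = 6.5e-51, median 23.4-fold with zeros at the floor; MAGEA4 at least 123-fold). Proliferation (1 of 37 higher, 19 lower, adjusted p = 0.0014, adjusted p = 0.11 with an estimated correlation; MCM6 log2 -0.75 ± 0.06) passed at the preset correlation alone. So did H3K36 genes (2 of 26 higher, 13 lower, adjusted p = 0.015, adjusted p = 0.24 with an estimated correlation; PSIP1 log2 -0.81 ± 0.09) and stress genes (15 of 24 higher, 3 lower, adjusted p = 7e-05, adjusted p = 0.14 with an estimated correlation; ATF3 log2 2.28 ± 0.12). PARP2 fell to 22.9 ± 3.5 from 34 ± 3 CPM (log2 -0.57 ± 0.11).

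In KO cells 5 days of the combination gave the highest count of any comparison with control, 11093 genes (6095 higher and 4998 lower, 3548 and 1074 by at least 2-fold; 4767 higher and 4794 lower without KO control replicate 2). GDF15 rose to 174 ± 2.1 from 4.2 ± 0.6 CPM (log2 5.37 ± 0.17, adjusted p = 3.2e-23), and CDKN1A to 445 ± 24 from 120 ± 5.8 CPM (log2 1.89 ± 0.09). The p53-induced noncoding gene PURPL rose to 98.6 ± 0.64 from 0.931 ± 0.48 CPM and RRM2B to 212 ± 7.7 from 49 ± 1.5 CPM. The replication helicase genes MCM6 (56.2 ± 0.78 against 163 ± 5.7 CPM, log2 -1.54 ± 0.06), MCM5 (log2 -1.38 ± 0.09) and MCM3 (log2 -1.03 ± 0.07) fell. So did UHRF1 (85.9 ± 0.5 against 157 ± 0.47 CPM), PARP1 (log2 -0.46 ± 0.07) and PARP2 (log2 -0.79 ± 0.11). COL5A1, AFAP1-AS1, ENG, CPA4, THY1, COL1A1 and KRT81 rose by log2 6.46 to 8.36. VAV3, MYH13, SEMA5B, ARHGAP6, LINC02532, IMPA2, ALDH1A1 and KMO fell by log2 values from -5.19 to -3.60. Of 27 p53 targets 19 were higher and 1 lower (adjusted p = 1.3e-10), and of 37 proliferation genes 0 were higher and 28 lower (adjusted p = 8.6e-12, median log2 -0.51). Interferon-stimulated genes (36 of 37 higher, 1 lower, adjusted p = 2.9e-44; IFI44 log2 4.32 ± 0.14) and NF-kB targets (28 of 33 higher, 3 lower, adjusted p = 3.2e-37; C3 417 ± 5.1 against 9.45 ± 1.4 CPM) rose. Cancer-testis genes had 40 of 41 higher and 1 lower (adjusted p = 3.6e-35, median 19.2-fold with zeros at the floor; PNMA5 at least 198-fold). Passing at the preset correlation alone were homologous recombination and Fanconi genes (7 of 44 higher, 21 lower, 7 and 24 adjusted over the list alone, adjusted p = 0.003, adjusted p = 0.14 with an estimated correlation; FANCD2 log2 -0.73 ± 0.06) and H3K36 genes (2 of 26 higher, 12 lower, adjusted p = 0.0057, adjusted p = 0.19 with an estimated correlation). The same held for MHC class I (13 of 17 higher, 2 lower, adjusted p = 0.00011, adjusted p = 0.072 with an estimated correlation) and DNA methylation machinery (1 of 17 higher, 9 lower, adjusted p = 0.026, adjusted p = 0.13 with an estimated correlation). Promoter-methylated genes had 16 of 30 higher and 9 lower (adjusted p = 0.005, adjusted p = 0.14 with an estimated correlation). Markers of blood and endothelial cells had 7 of 12 higher and 0 lower (9 adjusted over the list alone; adjusted p = 0.03, adjusted p = 0.056 with an estimated correlation), at low levels: ESAM 8.16 ± 0.11, TEK 2.67 ± 0.72 and CD3D 1.03 ± 0.43 CPM. With GC offsets the methylation machinery (adjusted p = 0.063) and blood marker (adjusted p = 0.12) calls ended, and DNMT1, lower at log2 -0.22 ± 0.07, turned to 0.03.

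The combination continued to change both lines after day 5. In WT, OAS2 reached 481 ± 0.23 CPM at day 26 (log2 12.11 ± 0.17), and IL6 327 ± 0.1 CPM at day 16 (log2 8.08 ± 0.15). ALDH1A1 fell to 3.6 ± 0.37 CPM at day 16 (log2 -7.81 ± 0.08), with CDH6 at 32.6 ± 2.1 against 567 ± 49 CPM. WT calls numbered 9682 at day 16 (5145 higher, 4537 lower) and 9257 at day 26 (5045 higher, 4212 lower), or 5127 at day 26 with only the contrast's libraries. Without WT control replicate 1 the balance turned at both days (4383 higher and 5005 lower, 4298 and 4711), as it did without combination replicate 1 at day 16 (4158 and 4237) or replicate 2 at day 26 (3927 and 4119). Hypoxia-inducible genes were higher in WT at day 16 (17 of 28 higher, 5 lower, adjusted p = 4.8e-11; CA12 775 ± 15 against 114 ± 5.6 CPM), and renal tubule genes split (7 of 18 higher, 8 lower, adjusted p = 0.0015). In KO, OAS1 reached 163 ± 1.3 CPM at day 16 and 88 ± 1.4 CPM at day 26, C3 601 ± 0.76 and 68.4 ± 4.1 CPM, and COL5A1 384 ± 6.2 and 259 ± 9.8 CPM. KO calls numbered 9604 (5212 higher, 4392 lower) and 7818 (4594 higher, 3224 lower), the latter 5205 without KO control replicate 2. In that fit the balance turned at both days (3532 higher and 4098 lower, 2437 and 2768), as it did with only the contrast's libraries (4426 and 4529, 3716 and 3827). It also turned without combination replicate 2 at day 16 (3631 and 3983) and without either combination library at day 26 (2630 and 2741, 2805 and 2956). Both KO libraries of day 26 stood apart on the first axis of a principal component analysis, at -9.8 and -9.9, against 41.8 to 82.7 in the other libraries given DAC and -94.2 to -67.2 in those without it. All 37 interferon-stimulated genes were higher at day 26 in WT (median log2 4.28) and in KO (median 3.04). Cancer-testis genes had 31 of 41 higher in KO, with a median rise of 4.6-fold with zeros at the floor.

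**Figure D2:**
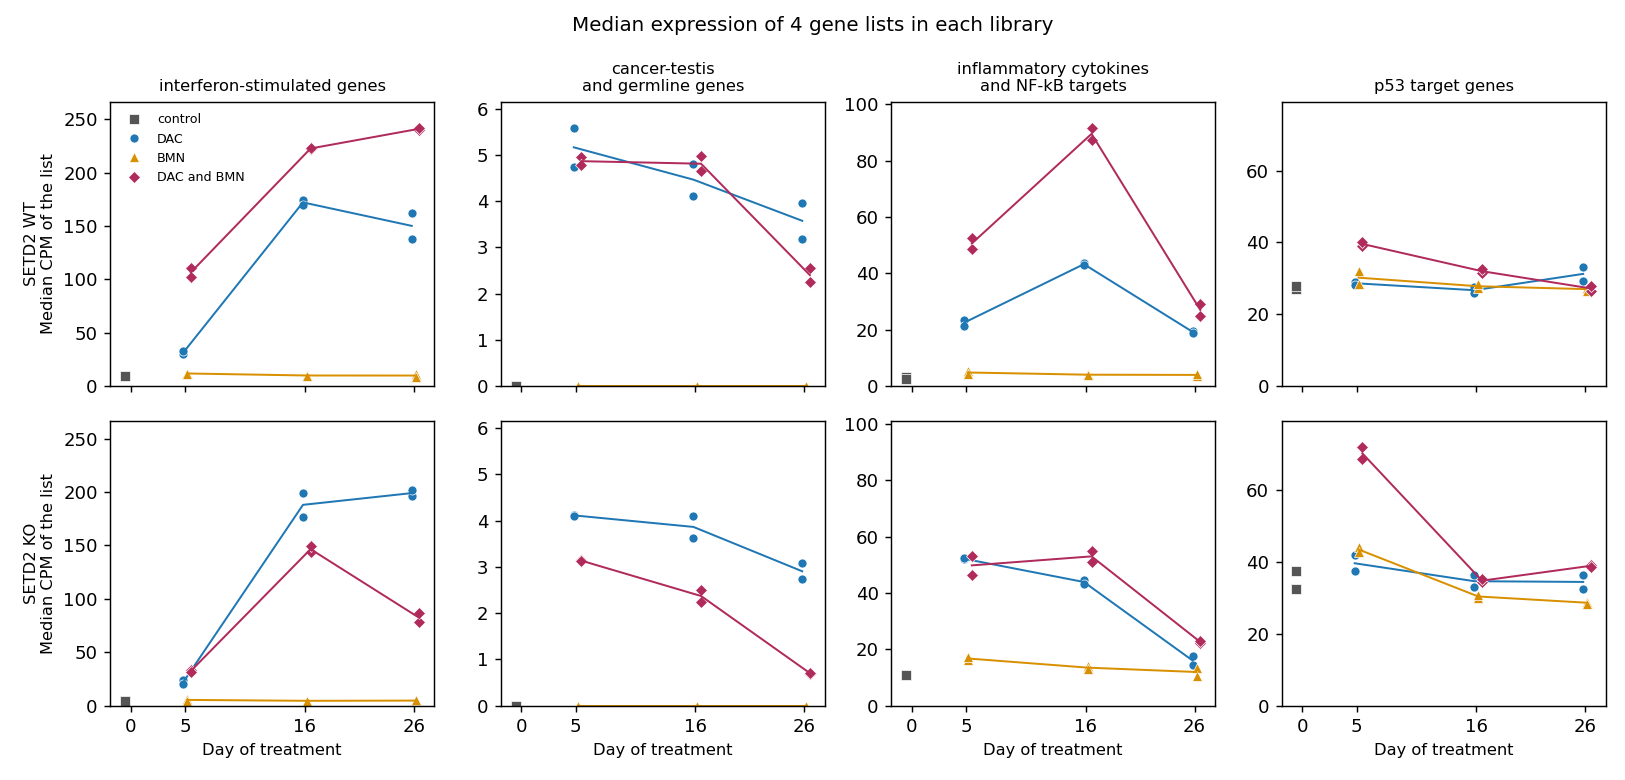
Median CPM of 4 gene lists in each library against day, on a linear axis, with WT above and KO below. Points are libraries and lines join group means. The interferon list is below its DAC level in both KO combination libraries of day 26 and above it in both WT libraries.

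The comparison of the combination with DAC, averaged over the 3 days, asked what the PARP inhibitor added. In WT the growth factor gene CSF2 averaged 12.2 against 1.37 CPM (log2 3.08 ± 0.15), IL6 159 against 23.9 CPM (log2 2.35 ± 0.06, adjusted p = 8e-25) and the interleukin gene IL1B 6.64 against 0.772 CPM. SPRY4, LINC02904, LINC01127, SCG5 and PTX3 were also higher (log2 2.03 to 2.92). ALDH1A1 averaged 49.8 against 339 CPM (log2 -3.35 ± 0.04), the muscle methyltransferase gene SMYD1 0.886 against 12.4 CPM (log2 -4.14 ± 0.16). CNN1, CHST9, PCSK5, ARHGAP6, PDZK1 and CDH1 were lower too (log2 -3.07 to -2.04). Of 5193 genes called 2307 were higher and 2886 lower (3352 and 3288 with GC offsets). Interferon-stimulated genes had 36 of 37 higher (37 adjusted over the list alone; adjusted p = 3.5e-139, median log2 0.96; OAS2 319 against 182 CPM) and NF-kB targets 29 of 33 higher (adjusted p = 6.1e-64; CXCL8 173 against 37.2 CPM). MHC class I had 16 of 17 higher (adjusted p = 1.4e-14) and nucleic acid sensing 11 of 16 higher and 2 lower (adjusted p = 1.5e-09). The p53 targets had 15 of 27 higher and 2 lower (17 and 2 adjusted over the list alone; adjusted p = 2.7e-07; GDF15 53.3 against 15.1 CPM). Cancer-testis genes had 3 of 41 higher and 15 lower (adjusted p = 0.042; MAEL log2 -0.72 ± 0.09), a call that ended with GC offsets (adjusted p = 0.11) and with days 5 and 16 only (adjusted p = 0.22). Hypoxia-inducible (9 of 28 higher, 7 lower, adjusted p = 0.00017, adjusted p = 0.15 with an estimated correlation; TGFA log2 0.72 ± 0.03) and stress genes (10 of 24 higher, 2 lower, adjusted p = 0.002, adjusted p = 0.28 with an estimated correlation) passed at the preset correlation alone. DNA methylation machinery (1 of 17 higher, 7 lower) and renal tubule genes (4 of 18 higher, 7 lower; CDH6 log2 -1.21 ± 0.04) each had adjusted p = 0.015 and an adjusted p = 0.097 with an estimated correlation.

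In KO the same contrast gave rises for GDF15 (70.5 against 11.8 CPM, log2 1.53 ± 0.09), the chromatin gene HMGA2 (41.1 against 14 CPM, log2 1.34 ± 0.08) and the EGFR ligand gene EREG (177 against 76 CPM), with CDKN1A at 249 against 141 CPM (log2 0.62 ± 0.05). COL5A1 was lower, at 298 against 943 CPM (log2 -1.59 ± 0.05), as were COL1A1 (482 against 1200 CPM) and MX1 (87.3 against 221 CPM, log2 -1.01 ± 0.05). Also lower were SMYD1 (log2 -2.75 ± 0.13), MGAT3, VWA1, MXRA8, LSP1, PTGIS, RCN3 and LAYN (log2 -2.17 to -1.88). Of 5127 genes called 2465 were higher and 2662 lower. Interferon-stimulated genes had 0 of 37 higher and 30 lower (0 and 32 adjusted over the list alone; adjusted p = 1.5e-26, median log2 -0.36). With days 5 and 16 only, 7 were higher and 8 lower (median -0.08, adjusted p = 0.62), and the calls of IFI27, IFIH1 and SAMHD1 ended. By single days the list was above DAC at day 5 (19 higher, 1 lower, adjusted p = 2.2e-09) and below it at day 16 (0 higher, 25 lower, adjusted p = 3e-27) and day 26 (0 higher, 35 lower, adjusted p = 7.8e-112), the day whose KO combination libraries stood apart. Nucleic acid sensing (0 of 16 higher, 8 lower, adjusted p = 3.4e-05) also ended with those days alone (adjusted p = 0.18). Cancer-testis genes had 0 of 41 higher and 33 lower (0 and 36 adjusted over the list alone; adjusted p = 1.9e-32, median log2 -1.07; MAEL log2 -1.60 ± 0.10, PNMA5 log2 -1.27 ± 0.08). MHC class I had 0 of 17 higher and 12 lower (adjusted p = 2.9e-11; HLA-F log2 -0.85 ± 0.06). Higher were p53 targets (17 of 27 higher, 0 lower, 21 and 0 adjusted over the list alone, adjusted p = 6.7e-14) and NF-kB targets (17 of 33 higher, 3 lower, adjusted p = 8.1e-12; IL6 152 against 77.2 CPM). Epithelial-mesenchymal (11 of 31 higher, 14 lower, adjusted p = 9.4e-06, adjusted p = 0.08 with an estimated correlation) and promoter-methylated genes (3 of 30 higher, 14 lower, adjusted p = 0.00065, adjusted p = 0.097 with an estimated correlation) passed at the preset correlation alone. So did hypoxia-inducible genes (11 of 28 higher, 4 lower, adjusted p = 0.0066, adjusted p = 0.35 with an estimated correlation).

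DAC and BMN, compared with each other over the same days, separated by the genes that DAC raised. COL5A1 averaged 591 CPM under DAC and 0.207 CPM under BMN in WT (log2 11.38 ± 0.10) and 943 against 0.787 CPM in KO (log2 10.28 ± 0.08), and MX2 107 against 0.539 CPM in WT (log2 6.92 ± 0.08). VAV3 was lower under DAC in WT (log2 -3.37 ± 0.15) and ALDH1A1 in KO, at 26.4 against 191 CPM (log2 -3.04 ± 0.04). Of 9608 genes called in WT 5245 were higher under DAC and 4363 lower, and of 11604 in KO 6420 and 5184. All 37 interferon-stimulated genes (median log2 3.0 in WT, adjusted p = 7.2e-253, and 3.27 in KO, adjusted p = 7.8e-216) and all 41 cancer-testis genes (adjusted p = 1.8e-83 and 4.7e-62) were higher under DAC. Proliferation genes were lower under DAC in KO (1 of 37 higher, 28 lower, adjusted p = 6.4e-06; CCNB1 log2 -0.48 ± 0.04) and, at the preset correlation alone, in WT (1 higher, 20 lower, adjusted p = 0.016, adjusted p = 0.24 with an estimated correlation).

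Whether the lines responded differently was tested by interaction terms averaged over days, in which a positive value is a log2 change under treatment that lay higher in KO than in WT, and a negative value one that lay lower. For DAC, 1988 genes passed, 824 positive and 1164 negative. CHRDL1 (log2 4.11 ± 0.19), SSC5D, KCNH2, COL6A3 (3.70 ± 0.08), OAS1 (3.66 ± 0.39), ENG and GNG4 had positive terms (log2 3.23 to 4.11). CHRDL1, GNG4, OAS1 and COL6A3 had started lower in KO, so their terms compare changes and not the levels reached. STEAP1B-AS1, TFCP2, TCEA3, DHRS3, SHISAL1 and TNF (log2 -2.15 ± 0.29) had negative terms, and TNF had started higher in KO. The call of INHBE (-2.60) was lost without WT control replicate 1 or KO control replicate 2. Terms of interferon-stimulated genes were shifted to positive values (11 of 37 positive, 2 negative, 14 and 5 adjusted over the list alone, adjusted p = 0.00011, median 0.10; IFI27 2.29 ± 0.16). So were those of epithelial-mesenchymal genes (14 of 31 positive, 5 negative, adjusted p = 2.9e-11; COL6A1 2.99 ± 0.12) and endogenous retroviral genes (4 of 12 positive, 0 negative, adjusted p = 0.0031; ERV3-1 0.69 ± 0.11). IFI27 had started lower in KO, while the median log2 difference of the interferon list at day 0 was 0.00. Terms of NF-kB targets were shifted to negative values (2 of 33 positive, 12 negative, 4 and 18 adjusted over the list alone, adjusted p = 4.1e-10, median -0.51), with CXCL8 at -1.52 ± 0.17. That list had started higher in KO (median log2 0.85 at day 0). Hypoxia-inducible (0 of 28 positive, 8 negative, adjusted p = 0.00031, adjusted p = 0.2 with an estimated correlation) and stress genes (0 of 24 positive, 7 negative, adjusted p = 0.00026, adjusted p = 0.21 with an estimated correlation) passed at the preset correlation alone. So did proliferation genes (1 of 37 positive, 8 negative, adjusted p = 0.00084, adjusted p = 0.14 with an estimated correlation). The DAC count was 3066 with GC offsets (1648 positive, 1418 negative), 1185 with days 5 and 16 only, 1208 without WT control replicate 1 (605 positive, 603 negative) and 3260 without WT control replicate 2.

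For BMN 276 genes differed in response, 28 positive and 248 negative. VAV3 (log2 -1.92), LINC02532 (-2.15) and NDRG1 (-0.92) fell more in KO. Hypoxia-inducible genes had 0 of 28 positive and 7 negative (2 and 13 adjusted over the list alone; adjusted p = 2.5e-10). Renal tubule genes had 0 of 18 positive and 3 negative (0 and 9 adjusted over the list alone; adjusted p = 8.9e-06; CDH6 -0.56). MHC class I had 0 of 17 positive and 1 negative (adjusted p = 8.9e-06, adjusted p = 0.083 with an estimated correlation). The p53 targets had 0 of 27 positive and 2 negative (adjusted p = 0.0048, adjusted p = 0.14 with an estimated correlation) and NF-kB targets 0 of 33 positive and 2 negative (adjusted p = 0.038, adjusted p = 0.28 with an estimated correlation). The BMN count was 77 without WT control replicate 1 and 2612 without WT control replicate 2, so it rests on those libraries. It lay between 118 (without KO control replicate 2) and 183 (without WT BMN day 16 replicate 2) without any 1 of WT BMN replicate 2 at day 5 or 26, KO BMN replicate 1 at day 5 or 26, or KO BMN day 16 replicate 2. For the combination 3200 genes passed, 1634 positive and 1566 negative. CHRDL1 (log2 3.83) and SSC5D (3.32) had positive terms, and TNF (-3.33), PTX3 (-3.32) and IL4I1 (-3.26) negative ones. MHC class I genes had 0 of 17 positive and 16 negative (adjusted p = 6.8e-30, median -0.77; TAP1 -1.49) and interferon-stimulated genes 3 of 37 positive and 22 negative (4 and 23 adjusted over the list alone; adjusted p = 1.1e-24, median -0.77; IFIT3 -1.60). NF-kB targets, which had started higher in KO, had 2 of 33 positive and 21 negative (adjusted p = 3.4e-28, median -0.91), with VCAM1 at -1.60. Nucleic acid sensing also had negative terms (0 of 16 positive, 10 negative, adjusted p = 2.2e-06), and endogenous retroviral genes positive ones (3 of 12 positive, 0 negative, adjusted p = 0.012; PEG10 0.71). Stress (0 of 24 positive, 12 negative, adjusted p = 1.4e-07, adjusted p = 0.075 with an estimated correlation) and hypoxia-inducible genes (3 of 28 positive, 8 negative, adjusted p = 2.8e-05, adjusted p = 0.11 with an estimated correlation) passed at the preset correlation alone. So did epithelial-mesenchymal genes (12 of 31 positive, 9 negative, adjusted p = 0.017, adjusted p = 0.36 with an estimated correlation). The median of cancer-testis genes was -0.88 although their test pointed up, and it did not pass (adjusted p = 0.45). The combination count was 1775 without WT control replicate 1 and 2085 without KO control replicate 2, and in 18 of 24 settings more terms were negative than positive, as with RLE size factors (1508 positive, 1681 negative) and days 5 and 16 only (1501 and 1858).

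**Figure D3:**
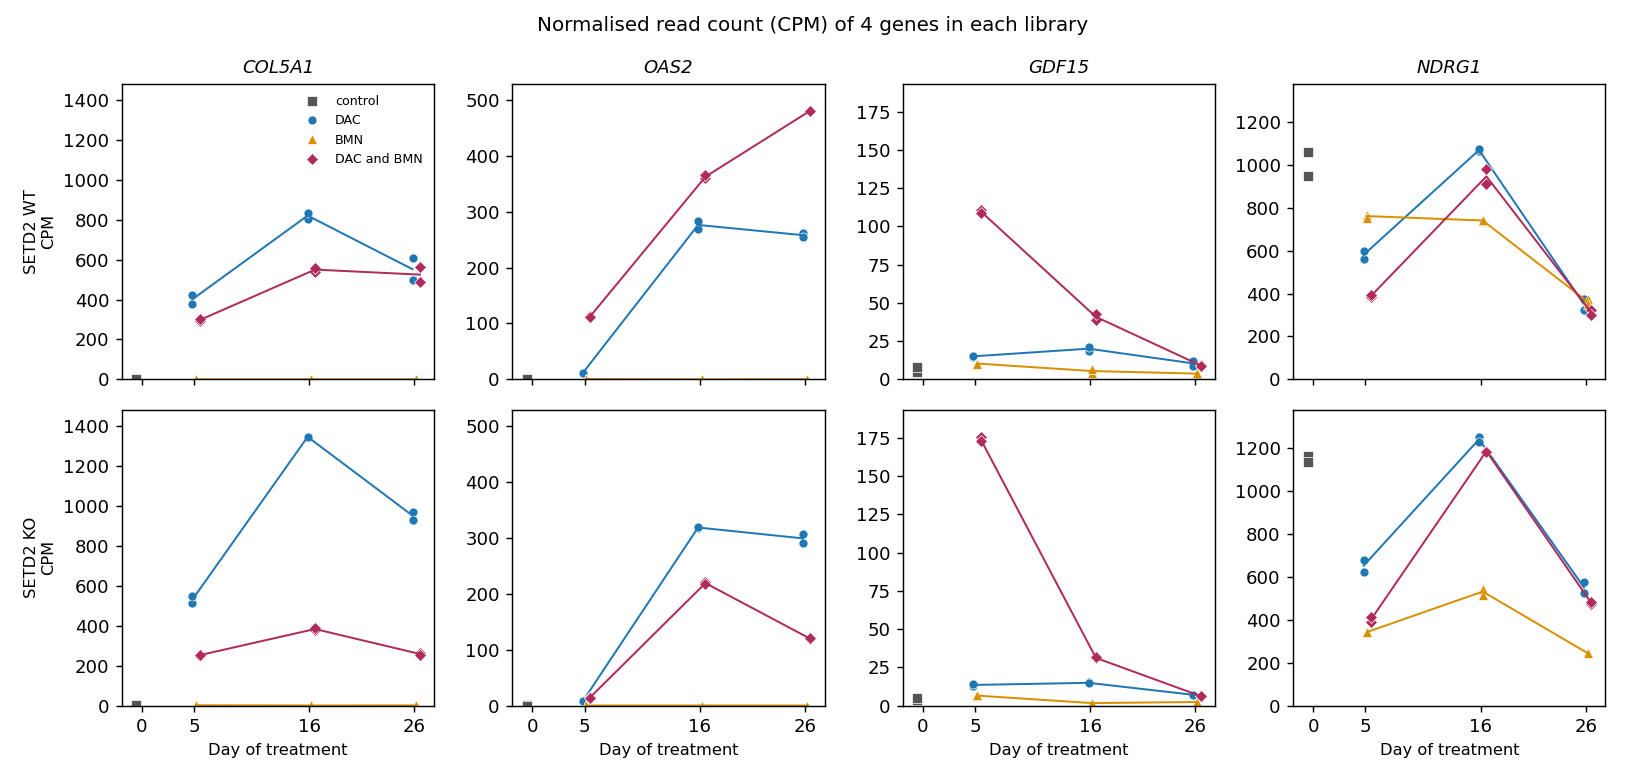
CPM of COL5A1, OAS2, GDF15 and NDRG1 in each of the 40 libraries against day, on a linear axis, by line and treatment. COL5A1 is below 1 CPM in every control library, and GDF15 is highest in the KO combination at day 5, at a mean of 174 CPM.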

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

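The library swap, the mixture of cells and the splits with the line difference removed were tested only after the result was seen, as were the GC offsets as a setting and the results with days 5 and 16 only.

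The response to treatment differed between KO and WT by a test of the difference itself in 1988 genes for DAC, 276 for BMN and 3200 for the combination. For DAC, among the genes with the largest differences were CHRDL1 (4.11), SSC5D (4.05), KCNH2 (3.78), COL6A3 (3.70), OAS1 (3.66), ENG (3.48) and GNG4 (3.23), whose log2 change under DAC lay higher in KO. Those whose change lay lower in KO were H4C13 (-3.85), INHBE (-2.60), STEAP1B-AS1 (-2.49), TFCP2 (-2.44), TCEA3 (-2.27), DHRS3 (-2.20), SHISAL1 (-2.18) and TNF (-2.15). H4C13 has near-identical copies and is uncertain, and the call of INHBE was lost without WT control replicate 1 or KO control replicate 2. Among these genes CHRDL1, GNG4, OAS1 and COL6A3 had started lower in untreated KO cells, and TNF and H4C13 higher. By list, the median difference for DAC was 0.10 in interferon-stimulated genes and -0.51 in NF-kB targets. For the combination it was -0.77 in interferon-stimulated genes, -0.77 in MHC class I presentation and -0.91 in NF-kB targets. The NF-kB list had started higher in untreated KO cells (median log2 0.85). Its terms, like those of the genes that started at unlike levels, compare changes and not the levels reached.

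Random splits of the libraries within day were compared with the real grouping, in fits with only the libraries of each contrast and 50 splits each, the real one included. For the combination against DAC in WT 1 split was as large, the real one, with 4514 genes against at most 1686 in the others. The same held for DAC against BMN in WT (1 split, 8405 against 4393) and in KO (1 split, 11543 against 7097). In KO the combination against DAC had 2 of 50 splits as large (real value 6327). The other one gave 6646 and kept both libraries of each group together, so that whole groups traded treatment. The median of the other splits was 0 genes in each of these comparisons. A split that mixes treatments within a group adds the treatment difference to the spread of that group, which lowers its count. The real grouping is therefore favoured, and these ranks do not exclude chance. For the differences in response between lines such splits could not decide either. Relabelling the lines day by day turns the difference between the lines, 6136 genes at day 0, into a difference in response. The 3 splits as large for DAC (real value 971, highest other 3908), 4 for BMN (96 and 6446) and 4 for the combination (2840 and 6820) all took it in, apart from the real one. The same splits were then run with the mean difference between the lines removed as an offset for each gene. For DAC 1 of 50 was as large, the real one, with 971 genes against at most 953 in the others. For BMN 2 of 50 were as large (real value 96), and 1 other split gave 160. The DAC margin was small and another BMN split was larger, so chance was not excluded for either. For the combination 1 of 50 was as large, the real one (2840 against 1656), which is only a rank among 50 splits.

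The first pattern weighed was a lower level of DAC-induced genes in KO cells under the combination at day 26. The 214 genes, chosen in WT cells by their rise under DAC against BMN, had medians of 2.56 and 2.62 CPM in those libraries, 7.1 and 7.41 CPM in KO under DAC alone and 6.82 and 7.49 CPM in WT under the combination. A swap with a KO BMN library was argued against, since the highest median there was 0.208 CPM, and so was GC content, since the difference from DAC was -1.55 with GC offsets and -1.45 without. A mixture of responding cells with cells like untreated ones cannot be told apart from a weaker response in all cells: among genes that had also responded in the KO reference group, induced genes kept 0.888 times the share of reduced genes with KO combination day 16 as reference (100 and 40 genes), and 0.597 times with KO DAC day 26 (122 and 22 genes), so the reference decides. A weaker lasting response in KO cells given both drugs stays open as a biological explanation that was not tested.

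The second pattern was that BMN changed more genes in WT at day 26 (5188) than at day 5 (42). GC content was argued against as the whole cause, since 5307 genes passed at day 26 with GC offsets. Whether the treated arms shared a drift of cells in culture could not be decided by correlating their changes over time. The response to DAC itself moved over these days, with the interferon list rising and the germline list falling. That can lower the correlation even where a drift is shared. The changes from day 5 to day 26 under BMN and under DAC had r = -0.0267 across 10462 genes with GC offsets, genes not being independent replicates. Without offsets r was 0.197 and the Spearman correlation 0.245. The correlation of expression with GC content itself moved with day, so the offsets can remove a shared drift that follows it, which stays open. A drift in the BMN arm alone cannot be separated from the drug with no untreated libraries at day 26. The day 26 count also rested on few libraries, with 2083 genes without WT control replicate 2, 2544 without BMN replicate 1 and 362 with only the contrast's libraries, and the day 5 count was 12 to 104 without any 1 library.

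The third pattern was that BMN at day 5 changed more genes in KO (2639) than in WT (42). With GC offsets 3082 genes passed in KO and 234 in WT, which argues against GC content as the whole cause, and without WT control replicate 1, the control library with the lower correlation of expression with GC content, 33 passed in WT, which argues against that library as the cause. Leaving out 1 library at a time gave 817 (BMN replicate 1), 1102 (control replicate 1), 1356 (BMN replicate 2) and 1698 (control replicate 2) in KO, and 12 (BMN replicate 1), 14 (BMN replicate 2) and 104 (control replicate 2) in WT. Averaged over days, 276 genes differed in their response to BMN, so a part of the pattern was tested as a difference, and that count was 77 without WT control replicate 1, 2612 without WT control replicate 2, and 118 to 183 without any 1 of the other libraries that moved it by more than 1.5 times. A stronger response of the KO line, whether from SETD2 or from another difference between the lines, may remain, and the data hold 1 line of each form.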

How the results depend on the processing

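GC offsets and days 5 and 16 only were chosen after the results were seen; the other settings were planned. In leave-one-out fits a lone library is assumed to vary like the other groups, and the filter on low counts was applied anew.

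All 28 counts of genes stayed within 1.5 times with RLE size factors and with the replicate block, where the count was 7833 for the KO combination at day 26 and 8128 for day 26 against day 5 of DAC in KO. Under DESeq2 26 of 28 stayed so, with the lane term 27, without a filter 25, with GC offsets 23 and with only the libraries of a contrast 17. That last setting has fewer samples to estimate spread and applies the filter on low counts anew. It gave 3181 genes for KO against WT at day 0, 2958, 4498 and 2392 for DAC in WT at days 5, 16 and 26, 362 for BMN and 5127 for the combination in WT at day 26, 1493 for day 26 against day 5 of DAC in WT, and 971 and 96 for the differences in response to DAC and BMN. For BMN in WT at days 5 and 16 it gave 0 and 0 by edgeR, against 1499 and 4223 genes at an unadjusted p below 0.05 with all 40 libraries. For the same 2 days DESeq2 gave 70 and 986, no filter 64 and 1348, GC offsets 234 and 570, and the lane term 55 at day 16. Without a filter the difference in response to BMN had 751 genes. GC offsets gave 2477 for BMN in KO at day 16, 3066 for the difference in response to DAC and 497 for that to BMN. Days 5 and 16 only gave 1185 and 134. The lower counts with only the libraries of a contrast do not follow from fewer samples alone. For BMN in KO that setting gave 3224 genes at day 5 and 6112 at day 16, above 2639 and 5749 with all 40. The lower counts given here all involved WT libraries, and replicates differed most in the WT controls (chi-square per degree of freedom 30.6). A fit of all 40 libraries shares its estimate of spread, so it can call too many genes in such groups. The cause was not tested further.

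Leaving out 1 library moved 33 of 180 counts by more than 1.5 times. For BMN in WT the range was 12 to 104 at day 5, 9 to 3987 at day 16 (3987 without WT control replicate 1) and 2083 to 6074 at day 26. For BMN in KO it was 817 to 1698, 2941 to 4326 and 4855 to 6243. It was 5205 to 6489 for the KO combination at day 26 and 2759 to 4792 for day 26 against day 5 of DAC in WT. For differences in response it was 1208 to 3260 (DAC), 77 to 2612 (BMN) and 1775 to 4763 (combination), each lowest without WT control replicate 1 and highest without replicate 2. The other counts stayed within 1.5 times. Which direction held more genes turned under at least 1 setting in 20 of 28 comparisons, in 8 of these only when a library was left out.

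Of 476 list results 393 kept their side of 0.05 with an estimated correlation and 83 lost the call. With GC offsets 432 kept it, 29 gained a call and 15 lost it, and with the replicate block 474 kept it and 2 gained a call. Among named genes 6 results changed sign: with GC offsets UHRF1 under DAC at day 26 in KO (0.08), DNMT1 at day 16 (0.20) and UHRF1 at day 26 (0.19) of BMN in KO, DNMT1 (0.03) and DNMT3B (0.23) under the combination at day 5 in KO, and, without WT control replicate 1, DNMT3B under DAC at day 26 in WT (-0.00, with a range to 0.41 without WT control replicate 2). The cause was not tested. Leaving out 1 library ended a call in 228 of 6272 results for named genes, and fitting only the libraries of the contrast in 64 of 949. Depth limits genes near the floor of 3 counts per library. In simulated data 65.7% of 1.5-fold changes were recovered, but only among well-counted genes, so that share does not cover genes near the floor.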

Other observations

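The tests of the combination against DAC at single days were chosen after the day-averaged results were seen.

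At day 5 the combination exceeded DAC in p53 targets in both lines, with 21 of 27 higher and 0 lower in WT (median log2 0.65, adjusted p = 2.7e-29) and 20 higher and 0 lower in KO (median 0.79, adjusted p = 4.1e-31). Both calls held with an estimated correlation (adjusted p = 4.6e-07 and 1e-06). In KO the difference was not called at day 16 (3 higher, 2 lower, adjusted p = 0.36) or day 26 (6 higher, 2 lower, adjusted p = 0.14). In WT 5 were higher and 2 lower at day 16 (adjusted p = 0.02, and 0.21 with an estimated correlation), and the difference was not called at day 26 (3 higher, 7 lower, adjusted p = 0.62). Proliferation genes in KO were lower than under DAC at day 5 (0 of 37 higher, 25 lower, median -0.37, adjusted p = 1.6e-17) and higher at day 26 (26 higher, 0 lower, median 0.33, adjusted p = 9.2e-13). At day 16 12 were higher and 0 lower (adjusted p = 0.00014, and 0.054 with an estimated correlation).

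Interferon-stimulated genes under the combination exceeded DAC in WT at each day (36, 19 and 30 of 37 higher and 0 lower, medians 1.73, 0.31 and 0.57). In KO they were above DAC at day 5 (19 higher, 1 lower, median 0.26, adjusted p = 2.2e-09), below it at day 16 (0 higher, 25 lower, median -0.37, adjusted p = 3e-27) and further below it at day 26 (0 higher, 35 lower, median -1.08, adjusted p = 7.8e-112). Cancer-testis genes in KO were below DAC at each day (1, 0 and 0 higher, 16, 22 and 33 lower, medians -0.52, -0.80 and -1.48). In WT they were below DAC at day 5 (0 higher, 5 lower, median -0.20, adjusted p = 0.01) and day 26 (1 higher, 11 lower, median -0.38, adjusted p = 0.0051). At day 16 in WT the list was not called (2 higher, 4 lower, adjusted p = 0.95). The calls by day numbered 2769, 2759 and 2746 genes in WT and 5030, 3666 and 5389 in KO, and with GC offsets 4062, 4169 and 4175 in WT and 6306, 4223 and 6682 in KO.

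For the 214 DAC-induced genes chosen in WT, the combination stood below DAC at day 26 in KO by a median of -1.45 (1 higher, 184 lower, p = 1e-112, and 5.2e-10 with an estimated correlation). In WT the median of these 214 genes was -0.13 (44 higher, 66 lower), for which camera gave 0.43, or 0.7 with an estimated correlation. The difference between the lines had a median of -1.30 (5 higher, 150 lower, p = 3.7e-64, and 6.4e-08 with an estimated correlation), and -1.46 with GC offsets. The WT DAC libraries of day 26 were among those that chose the genes. The WT value and the difference between the lines are therefore not independent of that choice, while the KO libraries took no part in it.

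The first axis of a principal component analysis held 40.7% of the variance and the second 20.4%. The KO combination libraries of day 26 stood apart on the first. The Spearman correlation of expression, relative to the mean of all libraries, with GC content was computed in each library. It ran from -0.54 to 0.52, and some libraries showed almost none (0.0042 in KO BMN day 5 replicate 1). The mean Spearman correlation across libraries of a day was 0.35 ± 0.27 (SD) at day 0, 0.25 ± 0.2 at day 5, -0.069 ± 0.25 at day 16 and -0.3 ± 0.27 at day 26. Comparisons with day 0 can therefore carry it along with the time in culture, to unlike degrees. Across these comparisons the Spearman correlation of log2 changes with GC content ran from -0.55 (BMN day 16 in KO) to 0.12 (combination day 5 in WT).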
